A study of Mus musculus with 8 samples.

How the data were processed

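Phosphorylated STAT3 was immunoprecipitated from mouse embryonic fibroblasts that re-expressed STAT3α or STAT3β, and the recovered DNA was sequenced. Per the labels' protocols, spliceform expression was induced with 1 nM 4-hydroxytamoxifen for at least 48 h, and serum was withdrawn 16 h before treatment with 10 ng/mL oncostatin M for 0, 30 or 180 min. Chromatin was cross-linked with 1% formaldehyde for 10 min and sonicated to fragments of 200 to 500 bp, per the labels' protocols. Input DNA of each cell line was also sequenced. The 6 ChIP samples had peak lists, and the 2 input samples entered no comparison.

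The submitters' processing notes name Trim Galore 0.4.2, STAR 2.5.0a, bedtools, MACS2 2.1.1.20160309 and HOMER 4.9, and the genome build mm9. The role of each tool, the threshold for a peak and the use of the input samples are not given in the sources used here. Per the labels, duplicates were prepared and the reads of a sample were merged, and 1 peak list per sample was deposited. Each list gives the chromosome, start, end and name of a peak. It holds no height, fold enrichment, p-value or read number, so the depth of the libraries is unknown and peaks could not be ranked by strength. Listed positions of 100 Mb and more in the 0 min lists had been rounded to 3 digits. This left 6 peaks (2 for STAT3α, 4 for STAT3β) known only to the nearest Mb, and these were left out of overlaps. Overlapping peaks of different lists had identical coordinates, so each list reads as membership in a common set of regions. How that set was built is not given in the sources used here.

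The gene table at hand belongs to GRCm38. Peaks of 6 chromosomes ended beyond the last gene of that assembly, for example at 196705790 on chromosome 1, so its coordinates were not used and sites were not assigned to genes. The planned tests of gene lists, of sites near transcription start sites, of genomic location and of the STAT3 recognition motif need a genome or annotation of mm9 and were not run. No score was listed, and peak width took its place where the design had named a score. The planned test of medians had nothing to compare, because nearly all peaks were 400 bp wide, and the share of wider peaks was counted instead. Width belongs to the common set of regions and does not measure signal in a list, so no test of it is reported.

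Groups were taken from the sample titles. A peak counted as shared when it overlapped a peak of the other list by 1 bp or more. Shares are given with 95% exact (Clopper-Pearson) binomial intervals, which cover counting over peaks only. Each overlap was compared with 1000 random placements of the peaks on their own chromosomes, between the first and last position listed on that chromosome. That null does not model open chromatin or mappability, so it sets a low bar. All 30 ordered pairs of lists were tested, and each reached the smallest adjusted p the placements allow, 0.001. Sets of sites were compared with Fisher's exact test, two-sided, and the listing of the same sites in both 180 min lists with an exact McNemar test. Benjamini-Hochberg adjustment ran over 12 comparisons of sites, random placements of single-list sites included, and separately over the 20 chromosomes. Chromosome shares were tested with 100000 permutations of the list labels. The comparisons of 180 min listing between shared and single-list sites and between spliceforms, of neighbouring sites and of chromosomes were added after the lists were seen. With 1 merged list per group, p-values compare libraries and sites, not cultures.

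Before the data were examined, the named sites were fixed as the 10 highest-ranked peaks of each 30 min and 180 min list, the 5 highest-ranked single-list peaks per spliceform and the 0 min peaks also listed at 30 min, with ties in genome order. The other sites named, common 180 min sites and 0 min sites missing at 30 min, were chosen after their values were seen. Alternatives to the overlap definition, to the chromosomes used and to the 0 min peaks were tried. The overlap and chromosome functions were tested on simulated data. All 500 of 500 planted shared peaks were recovered against the STAT3α 30 min list, in a simulated list of 1500 peaks. The planted peaks were exact copies of listed ones, so this checks the calculation and not the sensitivity to shifted peaks. The permutation test over all chromosomes called 5.5% of 200 random labellings of the 3060 single-list sites, and 100% of 200 runs with 3 chromosomes changed. The planted STAT3α shares were near the highest observed ones, so weaker changes were not tried. Fisher's exact test of each chromosome was not simulated. Labels were drawn independently over sites, so these rates do not cover clusters of neighbouring sites with the same label. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.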

Results

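Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map tyrosine-phosphorylated STAT3 on the genome of mouse embryonic fibroblasts. The fibroblasts lacked endogenous STAT3 and re-expressed a single spliceform of it from a tamoxifen-inducible construct. STAT3α is the full-length transcription factor, and STAT3β is the shorter spliceform that lacks the C-terminal transactivation domain. Cells were treated with oncostatin M, a cytokine of the interleukin-6 family that activates STAT3 through JAK kinases, for 0, 30 or 180 min. The data comprised 8 samples, of which 6 were ChIP samples with 1 peak list each and 2 were input DNA samples without a peak list used here. Each spliceform was represented by 1 cell line and 3 ChIP lists. Each list came from merged reads of a sample, so no value below has a replicate error across samples. The sequencing depth of the libraries is unknown from the peak lists, and the number of peaks depends on it. Positions are on mm9 and count from 1. No gene annotation of that build was used here, so sites are given by position and no gene is named.

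The first question was how far oncostatin M changed the number of sites bound by phosphorylated STAT3 over time. In STAT3α cells the list held 9 peaks without cytokine, 3725 peaks at 30 min and 40 peaks at 180 min. In STAT3β cells it held 12, 3891 and 120 peaks. The 30 min lists were thus 414 times (STAT3α) and 324 times (STAT3β) as long as the 0 min lists. By 180 min the lists had shrunk 93.1-fold in STAT3α cells and 32.4-fold in STAT3β cells, to 4.44 and 10 times the unstimulated number. The peaks at 30 min covered 1493 kb in STAT3α cells and 1561 kb in STAT3β cells. With 1 list per spliceform and time, no test across replicates was possible.

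**Figure D1:**
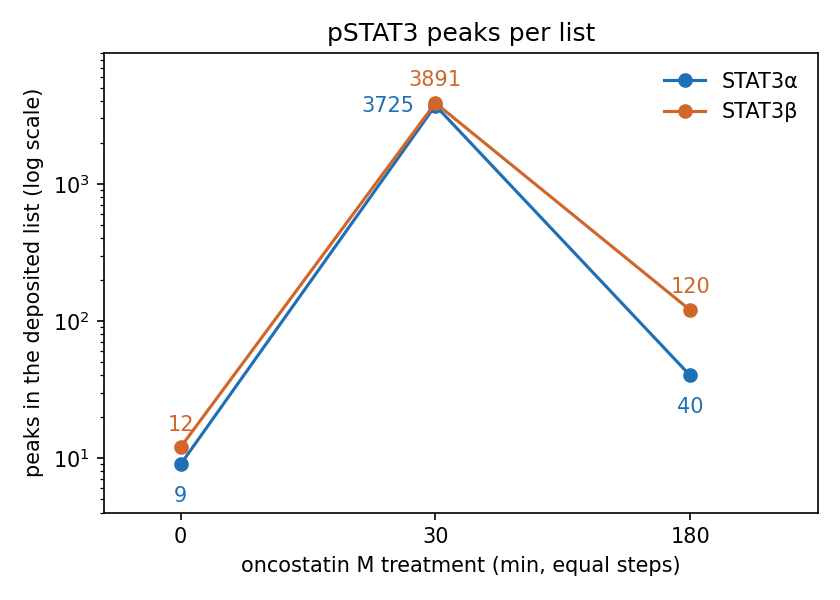
Number of peaks in each deposited list (y axis, log scale) against the duration of oncostatin M treatment in min (x axis, equal steps), with 1 list per point; the lines join lists of 1 spliceform. Both spliceforms peak at 30 min (3725 and 3891 peaks), and at 180 min the STAT3β list (120) is longer than the STAT3α list (40).

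The main comparison asked whether the spliceforms occupied the same sites at 30 min. The 2 lists together held 5338 sites, of which 2278 (42.7%) were in both, 1447 (27.1%) in the STAT3α list alone and 1613 (30.2%) in the STAT3β list alone. Shared sites made up 61.2% of the STAT3α list (95% exact binomial interval 59.6 to 62.7%) and 58.5% of the STAT3β list (57.0 to 60.1%). Random placement of the STAT3α peaks on their own chromosomes gave a mean of 5.04 overlapping peaks and a maximum of 14, against 2278 observed (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Every overlapping pair had identical start and end positions, in this and the other list comparisons, so overlap here is membership in a common catalogue of sites. Random placement does not draw from that catalogue. Its smallest possible p, here and in the other list comparisons, therefore says little about the spliceforms or the times. The intervals cover counting over peaks only. The lists do not tell why a site is missing from one of them, and its absence does not show that it was unbound.

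Nearly all 30 min peaks were 400 bp wide. Only 8 in the STAT3α list and 12 in the STAT3β list were wider, from 720 to 799 bp. All 8 of the wider STAT3α peaks were also in the STAT3β list. The widest ran from 111676564 to 111677362 on chromosome 5. It was followed by sites at 153457904 to 153458697 on chromosome 2, 17928151 to 17928929 on chromosome 16 and 6192407 to 6193179 on chromosome 13. The remaining wide shared sites were at 86385002 to 86385768 and 106077560 to 106078286 on chromosome 11, 32570954 to 32571717 on chromosome 13 and 63874718 to 63875437 on chromosome 15. The next STAT3α peaks in the ranking by width were 400 bp wide, at 6204852 to 6205251 and 6270325 to 6270724 on chromosome 1, and both were shared. The 4 wide sites listed for STAT3β alone lay at 12408402 to 12409196 on chromosome 6, 39945717 to 39946504 on chromosome 1, 52770937 to 52771696 on chromosome 13 and 64087497 to 64088247 on chromosome 17. The median width was 400 bp in both lists. Wider peaks were 0.351% of the shared sites, 0 of 1447 STAT3α-only sites and 0.248% of the STAT3β-only sites. Shared sites have the same width in both lists, so width is a property of the common catalogue and is not read here as a measure of signal. None of the 30 min peaks that were listed again at 180 min was wider than 400 bp.

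Single-list sites lay close to sites of the other spliceform more often than random placement gave. Of the 1447 STAT3α-only sites, 236 (16.3%) had a STAT3β peak within 10 kb, against 3.0% in random placements, and 617 (42.6%) had one within 50 kb, against 12.6%. Of the 1613 STAT3β-only sites, 246 (15.3%) had a STAT3α peak within 10 kb, against 2.92% in random placements, and 537 (33.3%) had one within 50 kb, against 12.1%. Each of the 4 comparisons had a one-sided permutation p of 0.001, the smallest that the placements can give (adjusted p = 0.0015). The placements do not model the clustering of peaks. Within 1 list, 18.6% of all STAT3α and 18.4% of all STAT3β 30 min peaks had another peak of that list within 10 kb. The closeness was thus not particular to sites of the other spliceform. The first STAT3α-only sites in genome order lay between 36613215 and 39771395 on chromosome 1, and the first STAT3β-only site of regular width lay at 3505053 to 3505452 on the same chromosome.

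The single-list sites were unevenly distributed between the spliceforms on 7 of the 20 chromosomes that carried peaks. STAT3α held 47.3% of all single-list sites. Its share was higher on chromosome 9 (68.1%, 98 against 46 sites), chromosome 19 (68.0%, 68 against 32), chromosome 7 (60.8%, 73 against 47) and chromosome 6 (59.5%, 91 against 62). It was lower on chromosome 10 (29.5%, 46 against 110 sites), chromosome 3 (30.1%, 66 against 153) and chromosome 15 (37.8%, 76 against 125). Adjusted p over the 20 chromosomes ranged from 2.2e-06 for chromosome 3 to 0.016 for chromosome 15 (Fisher's exact test of each chromosome against the rest). Over all chromosomes the chi-square statistic was 127 on 19 degrees of freedom (permutation p = 1e-05, the smallest that 100000 permutations can give). With 1 single-list site kept per 1 Mb, 2 chromosomes passed, chromosome 3 (26.8%) and chromosome 9 (64.2%), over 1310 remaining sites. In that draw chromosomes 10 (30.3%) and 19 (64.9%) had nearly the share of all sites but did not pass, chromosome 15 rose to 42.6%, and chromosomes 6 and 7 fell to 50.0%. Over 200 other draws 0 to 5 chromosomes passed. Chromosome 10 passed in 144 of them, chromosome 9 in 138, chromosome 3 in 136, chromosome 19 in 63, chromosome 15 in 5, and chromosomes 6 and 7 in none. This comparison was chosen after the positions had been seen, and it treats sites as independent.

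**Figure D2:**
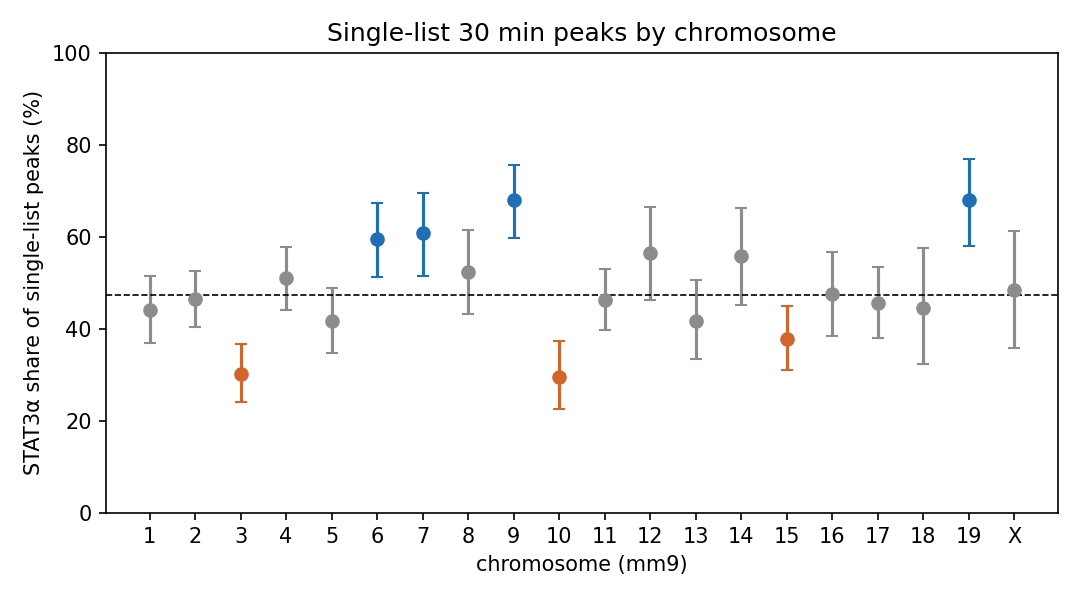
STAT3α share (%) of the 30 min sites listed for 1 spliceform only (y axis) on each mm9 chromosome (x axis), with 95% exact binomial intervals over sites; the dashed line is the share over all chromosomes, 47.3%. Blue marks the 4 chromosomes with a STAT3α excess, orange the 3 with a STAT3β excess, and grey the others at an adjusted p of 0.05 (Fisher's exact test), with sites treated as independent. With 1 site kept per 1 Mb, chromosomes 6 and 7 passed in 0 of 200 draws and chromosome 15 in 5.

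The time course was compared next within each spliceform, to ask whether late peaks were a part of the early ones. Of the 40 STAT3α peaks at 180 min, 35 (87.5%, interval 73.2 to 95.8%) were in the STAT3α 30 min list. Of the 120 STAT3β peaks at 180 min, 118 (98.3%, interval 94.1 to 99.8%) were in the STAT3β 30 min list. Random placements gave a mean of 0.057 and 0.173 peaks (one-sided permutation p = 0.001 for both). Some late peaks were already listed without cytokine. At exact positions, 5 of the 40 STAT3α and 5 of the 120 STAT3β peaks at 180 min were in the 0 min list of the same spliceform. In a comparison chosen after the lists were seen, late peaks came mainly from the sites shared by both spliceforms at 30 min. In STAT3α cells 35 of 2278 shared sites (1.54%) were listed at 180 min, against 0 of 1447 STAT3α-only sites, with an upper 95% limit of 0.255% (Fisher's exact test, adjusted p = 1.3e-07). In STAT3β cells 112 of 2278 shared sites (4.92%) were listed at 180 min, against 6 of 1613 STAT3β-only sites (0.372%; Fisher's exact test, adjusted p = 5.6e-19). These tests compare sites within the lists and do not measure variation between cultures. Strength is not listed, so whether shared sites were simply the stronger ones could not be tested. Late peaks also lay within the 30 min list of the other spliceform. This held for 37 of 40 STAT3α peaks (92.5%) and 112 of 120 STAT3β peaks (93.3%) at 180 min.

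**Figure D3:**
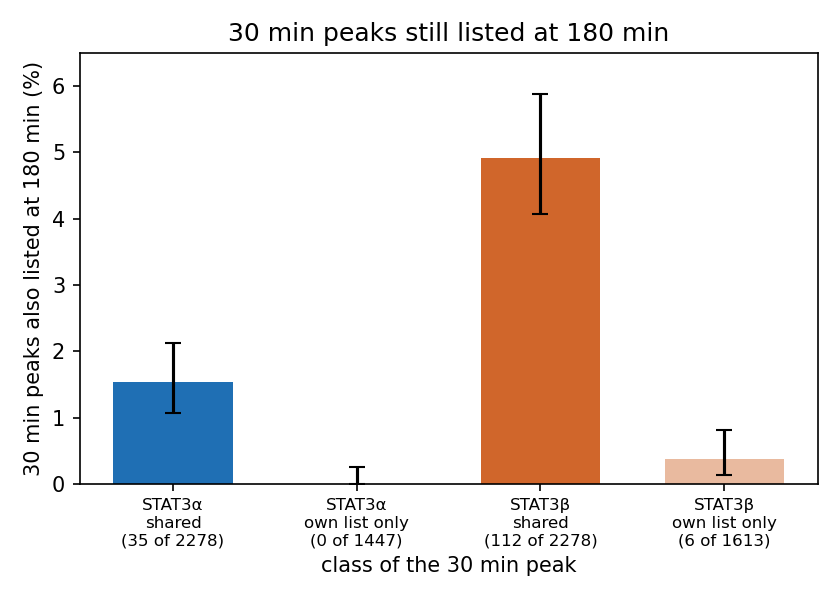
Share (%) of 30 min peaks that were also in the 180 min list of the same spliceform (y axis), for peaks shared by both spliceforms at 30 min and for peaks in that spliceform's list alone (x axis); bars start at 0 and error bars are 95% exact binomial intervals over sites. Shared sites were listed at 180 min in 1.54% (STAT3α) and 4.92% (STAT3β) of cases, and single-list sites in 0% and 0.372%.

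The spliceforms were then compared at 180 min. The lists had 27 sites in common, which was 67.5% of the STAT3α list (interval 50.9 to 81.4%) and 22.5% of the STAT3β list (15.4 to 31.0%). Another 13 sites were in the STAT3α list alone and 93 in the STAT3β list alone. All 27 common sites were in both 30 min lists. Among the 2278 sites shared at 30 min, independent choice would have put 1.72 in both 180 min lists, against 27 observed (Fisher's exact test, adjusted p = 3.8e-29). That null gives every shared site the same chance of being listed. Sites could not be ranked by strength, so the excess does not show a choice made by the spliceforms. Of the 27 common sites, 4 were also in a 0 min list at an exact position. Of these 2278 sites, 85 were listed at 180 min for STAT3β only and 8 for STAT3α only (exact McNemar test, adjusted p = 9.2e-17), which compares these libraries and not the conditions. Most peaks of both 180 min lists lay at these sites, so the McNemar test largely restates the list lengths, 120 against 40. The STAT3β list held more 180 min peaks on each of the 20 chromosomes. Without sites at an exact 0 min position, the 180 min lists held 32 STAT3α and 115 STAT3β peaks. Leaving out also every peak in the same Mb as a rounded 0 min position gave 28 and 110. That removes more than the rounded peaks themselves, whose exact positions are unknown.

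The 27 sites common to both 180 min lists were spread over 15 chromosomes. In genome order they began with 88422734 to 88423133 on chromosome 1, followed by sites starting at 160051121, 164258134 and 167602937 on chromosome 2. Chromosome 3 had sites starting at 65331908 and 107563034, and chromosome 4 had sites starting at 133369662, 151236381 and 151699618. Chromosome 11 carried 4 of them, at 74651938 to 74652337, 100800888 to 100801287, 117830560 to 117830959 and 121534294 to 121534693. Chromosome 15 carried 3, starting at 6824175, 38400117 and 76456294. Among the first 10 STAT3α peaks at 180 min in genome order, 2 were not in the STAT3β list, at 132651046 to 132651445 on chromosome 4 and at 33946114 to 33946513 on chromosome 2. The latter was also in the STAT3α 0 min list and in neither 30 min list. Among the first 10 STAT3β peaks at 180 min, those starting at 52170535 on chromosome 1 and at 30297184, 35955264, 104333611, 120796273, 150735344 and 167088795 on chromosome 2 were not in the STAT3α list.

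The unstimulated lists gave the background of the experiment. Position was rounded to the nearest Mb for 2 STAT3α and 4 STAT3β peaks at 0 min. The 0 min lists shared 4 peaks, which was 57.1% of the 7 STAT3α peaks with an exact position (interval 18.4 to 90.1%) and 50.0% of the 8 such STAT3β peaks (15.7 to 84.3%). No rounded position was in both lists, so over all listed peaks the shares were 44.4% and 33.3%. The peaks of exact position made up 11 distinct sites, of which 9 were in either 30 min list, 8 in both, and 9 in either 180 min list. In STAT3α cells 4 of 7 such peaks (57.1%, interval 18.4 to 90.1%) were listed at 30 min, and in STAT3β cells 7 of 8 (87.5%, interval 47.3 to 99.7%). A single site, at 4988979 to 4989378 on chromosome 19, was in all 6 lists. The sites at 87500257 to 87500656 on chromosome 8 and at 6824175 to 6824574 and 38400117 to 38400516 on chromosome 15 were in every list except that of unstimulated STAT3α cells, where no rounded peak lay on those chromosomes. The site at 21754768 to 21755167 on chromosome 9 was missing only from the STAT3β 180 min list. The site at 24999947 to 25000346 on chromosome 11 was in the 0 and 30 min lists of both spliceforms and in neither 180 min list. The site at 72398960 to 72399359 on chromosome 15 was in all 3 STAT3α lists and in the STAT3β list at 30 min. The site at 4626165 to 4626564 on chromosome 17 was in the STAT3β 0 min list and both 30 min lists. The site at 14072529 to 14072928 on chromosome 8 was in the STAT3α lists at 0 and 180 min and, at 30 min, in the STAT3β list alone. The site at 84659817 to 84660216 on chromosome 15 was in both 0 min lists and the STAT3β 180 min list and in neither 30 min list. With 7 and 8 peaks the shares are imprecise.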

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

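Both tests of explanations here were chosen after the result was seen. A difference between the STAT3α and STAT3β lists stood out at 180 min. Among the 2278 sites shared at 30 min, 4.92% were listed at 180 min for STAT3β and 1.54% for STAT3α, a difference of 3.38 percentage points (exact McNemar test, adjusted p = 9.2e-17), with 85 sites listed for STAT3β only and 8 for STAT3α only. Most peaks of both 180 min lists lay at these sites, and the lists held 120 and 40 peaks. The McNemar test thus largely restates list length. The longer STAT3β list was not confined to chromosomes where STAT3β held more single-list 30 min sites. On the 8 chromosomes where STAT3α held at least as many single-list 30 min sites as STAT3β, the STAT3β list still had 2.5 times as many 180 min peaks (35 against 14, exact binomial p = 0.0038). The null was equal numbers, and over all chromosomes the STAT3β list was 3 times as long. The binomial p therefore does not measure a difference from the other chromosomes. Fewer usable reads in the STAT3α 180 min library could also shorten its list. The lists hold no depth to decide it, and the share of STAT3α 180 min peaks in the STAT3β list, 67.5%, does not, since the share that a shallower library would give is unknown. Depth, cell line and spliceform cannot be told apart here, with 1 cell line per spliceform. A difference between the spliceforms stays open, untested.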

How the results depend on the processing

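Of 57 alternative values for 24 results, 55 kept their direction and their side of the threshold, or moved by less than the set limits. Of these, 4 concern peak width, which does not measure signal, and say nothing about stability. Another 36 are overlap shares, nearly all counted as kept because the placement p stayed at its smallest possible value. That p sets a low bar, so the count does not measure how far the shares moved. Chosen after seeing the data were the 5 kb and 50 kb distances, the uses of rounded 0 min positions, and every alternative for chromosome shares and for the 180 min listing of shared and single-list sites. The exception was the number of chromosomes with an uneven share of single-list sites, which went from 7 to 2 when 1 site was kept per 1 Mb, with 1310 of 3060 sites left, and to a median of 3 over 200 other draws (range 0 to 5). The permutation p over all chromosomes was 0.00025 in the first draw and at most 0.022 in the others. The median STAT3α share over those draws was 28.8% on chromosome 10 and 67.6% on chromosome 19, against 29.5% and 68.0% of all sites. On chromosomes 6 and 7 it was 54.1% and 55.0%, against 59.5% and 60.8%, and on chromosome 15 it was 40.4% against 37.8%. Requiring 0.5 of each peak to overlap, or restricting the lists to chromosomes 1 to 19 and X, moved no share, because shared peaks have identical coordinates and no other chromosome is listed, so these settings say nothing about stability. The share of the STAT3α 30 min list that was shared rose from 61.2% to 65.1% within 5 kb and to 77.7% within 50 kb, where random placements gave 1.6% and 12.9%. For STAT3β it rose from 58.5% to 62.9% and 72.3%. The stricter thresholds and the lists of equal length could not be run without a score, and neither could the gene, motif and location alternatives without mm9. No 0 min list was recomputed without its own peaks. No paired analysis was possible because each group has 1 merged list. Unknown depth limits every comparison of list lengths.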

Other observations

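The tests of chance scatter, of the longest run and of the number of cell lines were chosen after the results were seen, and so were the correlations without 2 chromosomes and the repeated draws of 1 site per 1 Mb. The correlation of log2 ratios was not the measure set before the test, and is no further evidence beside that of shares. The 30 min sites were most dense on chromosome 11 (3.61 sites per Mb of the stretch between its first and last listed site) and chromosome 15 (3.55), and least dense on chromosome X (0.678), against 2.1 over all 20 chromosomes. The densest 100 kb windows were chosen by their number of sites. The first lay on chromosome 11 from 117784693 to 117856935 and held 12 sites, 11 of them in the STAT3α list and 9 in the STAT3β list, and it also held 1 STAT3α and 2 STAT3β peaks at 180 min. The next, on chromosome 10 from 79533900 to 79621584, held 10 sites, 6 for STAT3α and 9 for STAT3β. A window on chromosome 12 from 70512992 to 70603441 held 9 sites, all in the STAT3α list and 5 in the STAT3β list. A window on chromosome 17 from 35857387 to 35950565 held 9 sites as well, 8 for STAT3α and 5 for STAT3β. A window on chromosome 5 from 91110969 to 91193504 also held 9 sites, 4 for STAT3α and 8 for STAT3β. Among the windows with 8 sites, one on chromosome 2 from 167586158 to 167660483 had 7 shared sites and 1 site common to both 180 min lists. In the STAT3α 30 min list 18.6% of peaks had another peak of that list within 10 kb, and in the STAT3β list 18.4%.

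A hypothesis was that sites still listed at 180 min sit in clusters of 30 min peaks. In STAT3α cells 6 of 35 such sites (17.1%) had another 30 min peak within 10 kb, against 18.6% of the other 30 min peaks. In STAT3β cells it was 24 of 118 (20.3%) against 18.3%. The test did not bear the hypothesis out (Fisher's exact test, smaller p = 1 after adjustment over both spliceforms), though 35 sites limit its precision.

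The uneven chromosome shares of single-list 30 min sites would merit a second look, because a difference that follows whole chromosomes may reflect the cell lines and not the spliceforms. Random scatter was the null of the test that showed the pattern (permutation p = 1e-05, the smallest possible), so that value is no separate evidence. Local clusters within 1 Mb are argued against as the whole cause (permutation p = 0.00025 with 1 site kept per 1 Mb, and at most 0.022 in 200 other draws). A whole-chromosome difference between the lines, such as copy number, stays open and had the relation it needs: the STAT3α share among the proximal single-list sites of a chromosome correlated with that among its distal ones, split into about equal numbers, over 20 chromosomes (Pearson r = 0.48, permutation p = 0.032; Spearman rho = 0.41, permutation p = 0.074), and log2 ratios in place of shares gave r = 0.49 (permutation p = 0.027). The relation is weak, since r ranged from 0.286 (without chromosomes 3 and 10) to 0.643 over the 190 ways to leave out 2 chromosomes and p was above 0.05 in 81 of them; without chromosomes 9 and 19, farthest from the median, r was 0.324 (permutation p = 0.19). Shorter stretches also stay open: the longest run, 20 STAT3α-only sites on chromosome 19 from 7131941 to 22990753 with no STAT3β-only site but 8 shared sites in the stretch, was reached in permutations within chromosomes with p = 0.075. A choice of sites by the spliceform itself cannot be told apart from the cell line, since there was 1 line per spliceform; read coverage of the input samples, not analysed here, would bear on copy number.

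The 6 rounded 0 min positions each had between 1 and 21 sites of the 30 min lists in the same Mb, and 4 of them had a 180 min peak there.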
